A study of Hemigymnus melapterus and Thalassoma lunare and Coris batuensis with 46 samples.

How the data were processed

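The measured material was a section of the forebrain of 46 female wrasses of 5 species, 1 library per fish. Per the labels' protocols, heads were placed in RNAlater, the time between capture and death ran from 6 to 28 minutes, the frozen heads were cut into slices of 300 µm, and RNA was extracted with a Maxwell kit that includes a DNase step. Libraries were made by a 3′ tag protocol with poly-dT priming and PCR and were sequenced on a HiSeq instrument, per the labels' protocols. The labels mention no molecular identifiers, so PCR copies may be counted more than once and spreads and intervals derived from counts alone would cover counting error only.

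The submitters' processing notes name cutadapt 2.8, BWA and SAMtools, without saying which step each made. The reference sequences and the counting tool are not given in the sources used here. For each fish the authors deposited 2 tables of raw read counts, and neither was normalized, judging from the values, which are whole numbers with a different total in each library. One lists 26788 identifiers that begin with ENSONIT, plus 1 unnamed line that held 0 counts over all libraries. The other lists 28134 identifiers that begin with Ldim_g plus 5 lines for reads not given to a gene. Over all 32137144 reads in these second tables, 56.0% were listed as not aligned, 36.6% as aligned outside any gene, 2.57% as aligned with too low quality, 0.00483% as ambiguous, 0% as not unique, and 4.81% were counted in genes. The lines that name no gene were left out of library sizes and of all tests. All 5 species were counted on the same identifiers in each set, so a transcript whose sequence differs more from the reference in one species can lose reads in that species, and a count then reflects alignment as well as abundance. The ENSONIT counts were the main set and the Ldim_g counts an alternative, a choice made, like the tests and the other settings listed here unless stated otherwise, before the data were examined.

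The files do not pair the identifiers with gene symbols, and no reference or table of names was used here. Gene lists fixed beforehand could therefore not be tested, and at most 2 identifiers per direction are printed. The rule for named features was to take up to 12 per direction, among those with the same direction and an adjusted p below 0.05 in all 6 comparisons of a cleaner with a non-cleaner species and a mean of at least 1 CPM in a status, by the largest smallest absolute fold change. It gave 8 that were higher, of which the first 2 are named, and none that was lower, so the 2 largest falls past the threshold of the status contrast were named instead, chosen after their values were seen.

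Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with species as the group (minimum count 10, minimum total count 15), which left 720 ENSONIT transcripts and 753 Ldim_g genes. Library sizes were recomputed over these features and scaled by TMM, so CPM is relative to the tested features. A quasi-likelihood model with 1 coefficient per species was fitted to all 46 libraries, which share 1 estimate of spread (biological coefficient of variation 0.285). From it came the status contrast (the mean of 3 cleaner species minus the mean of 2 non-cleaner species), the 10 species pairs, and the features that passed in all 6 cleaner with non-cleaner pairs in 1 direction. Standard errors of log2 fold changes were derived from the fold change and its F statistic. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The species-level test was limma 3.58.1 (lmFit, eBayes with trend) on 5 species means of log2-CPM with a prior count of 2. Library measures were compared by two-sided permutation tests over fish with 100000 resamples and by the exact permutation of 5 species means, and 12 such measures were adjusted together. The labels number the fish within each species, with numbers that recur across species, and state no batch, so no comparison within stated batches could be made.

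Alternatives were the Ldim_g counts, other normalizations (DESeq2 size factors and upper quartile), the DESeq2 1.42.0 Wald test, no filter on low counts, a filter on a median of at least 1 CPM in each species, a minimum absolute log2 fold change of 1, leaving out each species, the species as a random block in limma-voom, a block on the sample number, and thinning of all libraries to 6936 counts. Leaving out the 3 libraries that stood apart, leaving out Coris batuensis 10 and the species-level test on the Ldim_g counts were added after seeing the data. No library was relabelled in any reported comparison, apart from trial exchanges of labels between Halichoeres and Thalassoma.

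Within each species, all pairs of libraries (190 in each set) were checked for a library present more than once, by identical values and by a chi-square test over features with at least 20 counts. None was identical, and the highest p was 8.61e-09 in the ENSONIT counts and 0.00592 in the Ldim_g counts, so no pair differed by counting error alone. With PCR copies among the reads this does not rule out a second library of the same fish, and each library was taken as 1 fish from the labels. The edgeR steps were tested on simulated data drawn from the real means, spreads and library sizes of the 720 transcripts, with no species effect and 200 transcripts changed by status. For the status contrast, 95% of the 100 transcripts changed 2-fold and 100% of the 100 changed 4-fold were called in the right direction, and 3.94% of the calls were of unchanged transcripts. The demand for all 6 pairs recovered 64% of those changed 2-fold and 95% of those changed 4-fold, and no unchanged transcript. As the simulation held no species effect, these rates do not carry over to the real status contrast, where species differ within a status.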

Results

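The series profiled one forebrain section from 46 female wrasses of 5 Labridae species by 3′ tag sequencing, in which 1 end of each polyadenylated transcript is read so that counts scale with transcript number. The labels call 3 species facultative cleaners, fishes that sometimes remove parasites from other fishes: Halichoeres melanurus (9 fish), Hemigymnus melapterus (10 fish) and Thalassoma lunare (10 fish). They call 2 species non-cleaners: Coris batuensis (9 fish) and Labrichthys unilineatus (8 fish). The section was a 300 µm slice that held the pallial areas Dl and Dm, regarded as fish counterparts of the hippocampus and the basolateral amygdala, and part of the septal and striatal areas. The comparison of interest, from the title of the series and its labels, was between species that clean and species that do not. Cleaning status varied only between species, so the fish of a species repeat that species and not the status, and p-values over fish describe these 5 species.

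Assigned counts were low. Counts assigned to ENSONIT transcripts, the counts used for the main comparisons, ranged from 6936 to 53987 per library. The second set listed 86674 to 1111736 reads per library in all, so few assigned counts do not by themselves mean few sequenced reads. The mean was 32912 ± 7279 (SD, n = 9) in Halichoeres, 24990 ± 9512 (SD, n = 10) in Hemigymnus, 43819 ± 4996 (SD, n = 10) in Thalassoma, 29918 ± 6161 (SD, n = 9) in Coris and 37892 ± 10279 (SD, n = 8) in Labrichthys. Of the 25328 transcripts with at least 1 count in some library, 720 had enough counts to be tested. These 720 transcripts held 57.8% of all counts. A single count in the median library corresponded to 52.8 CPM, the count scaled to a common library total. Cleaners and non-cleaners had similar depth, with 33941 ± 10773 counts (SD, n = 29) against 33670 ± 9058 (SD, n = 17), and a two-sided permutation test over fish gave p = 0.931 (Benjamini-Hochberg adjusted p = 0.985 over 12 library measures). Transcripts detected per library were also close, at 7808 ± 1881 (SD, n = 29) and 7752 ± 1071 (SD, n = 17), permutation p = 0.911 (adjusted p = 0.985).

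The second set of counts, on genes with Ldim_g identifiers, also recorded reads outside genes. The share of reads left unaligned there differed between species. It was 61.1% ± 1.31 (SD, n = 10) in Thalassoma, 59.1% ± 1.46 (SD, n = 9) in Halichoeres, 58.1% ± 0.594 (SD, n = 9) in Coris, 50.9% ± 2.04 (SD, n = 10) in Hemigymnus and 47.0% ± 1.21 (SD, n = 8) in Labrichthys. By status it was 57.0% ± 4.81 (SD, n = 29) in cleaners and 52.9% ± 5.76 (SD, n = 17) in non-cleaners. Permutation over fish gave p = 0.0138 (adjusted p = 0.166 over the 12 measures), and the exact permutation of the 5 species means gave p = 0.5, where the smallest possible p is 0.1.

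Libraries grouped by species. In both sets of counts 44 of the 46 libraries correlated best with the mean of the other libraries of their own labelled species (Pearson r across the tested features, which are not independent replicates). The exceptions were the same 2 libraries in both sets. The library labelled Thalassoma lunare 4 had r = 0.949 with the mean of Halichoeres and r = 0.742 with its own labelled species in the ENSONIT counts, and 0.957 and 0.776 in the Ldim_g counts. The library labelled Halichoeres melanurus 2 had r = 0.935 with the mean of Thalassoma and r = 0.714 with its own labelled species in the ENSONIT counts, and 0.945 and 0.756 in the Ldim_g counts. Both species are facultative cleaners, so no doubt about these 2 labels touches the status of a fish. Another library, labelled Hemigymnus melapterus 4, was nearest to its own species but at r = 0.544 in the ENSONIT counts, where the other Hemigymnus libraries lay between 0.901 and 0.938. It had the lowest count of all libraries, 6936, and detected 1676 transcripts, where the other libraries of its species detected 5205 to 8351. All labels were kept as deposited, and values without these 3 libraries are given where stated.

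**Figure D1:**
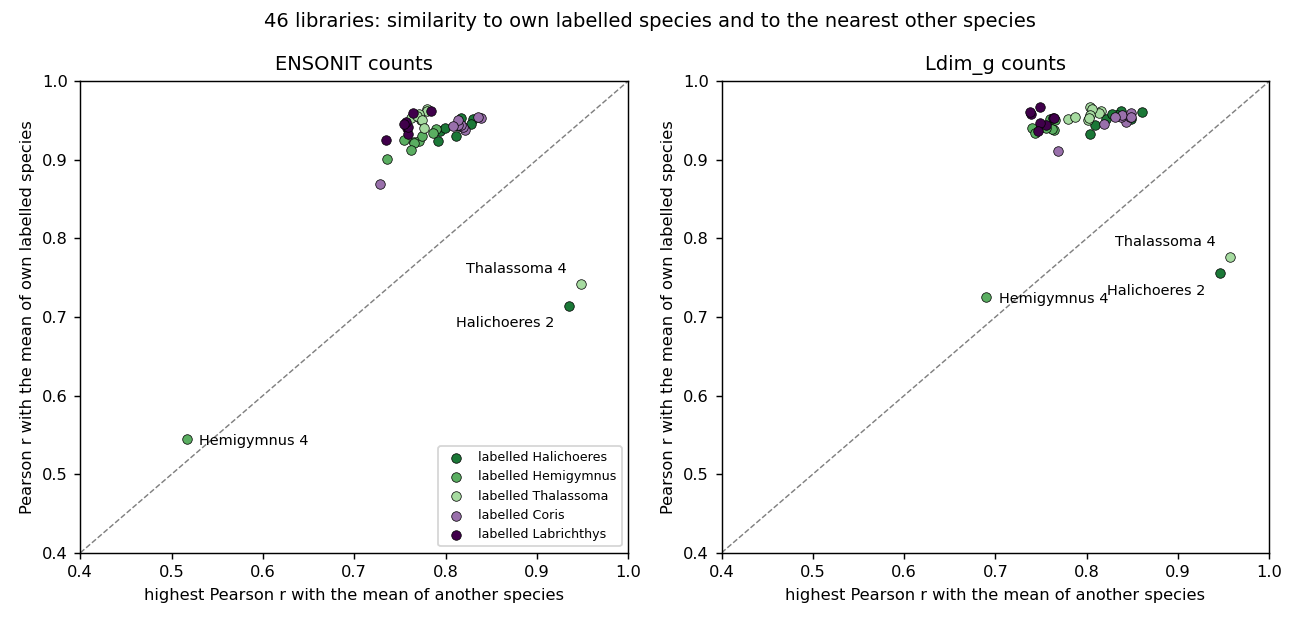
Pearson r of each of the 46 libraries with the mean of the other libraries of its labelled species (vertical axis, no unit) against its highest r with the mean of another species (horizontal axis, no unit), for the ENSONIT counts (left) and the Ldim_g counts (right), with points coloured by labelled species and a dashed line of equal values. The libraries labelled Thalassoma 4 (0.742 on the vertical axis at left) and Halichoeres 2 (0.714) lie below the line in both panels, and Hemigymnus 4 (0.544) lies far from the rest of its species.

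Among the 720 tested transcripts, ENSONIT00000019535.1 had the largest fold change between facultative cleaners and non-cleaners. It averaged 789.9 ± 171 CPM (SD, n = 9) in Halichoeres, 865 ± 424 CPM (SD, n = 10) in Hemigymnus and 982 ± 189 CPM (SD, n = 10) in Thalassoma, and 47.9 ± 52.8 CPM (SD, n = 9) in Coris and 42.4 ± 53.9 CPM (SD, n = 8) in Labrichthys. The log2 fold change, cleaner species minus non-cleaner species with each species weighted equally, was 4.04 (SE 0.25, edgeR quasi-likelihood adjusted p = 2.68e-19). The raw counts behind it were 138, 143 and 247 in the 3 cleaner species and 8 in each non-cleaner species. In 28 of 29 cleaner fish its CPM was above that of all 17 non-cleaner fish, and the exception was the shallow library labelled Hemigymnus melapterus 4, with 0 counts. The largest value in a non-cleaner fish was 172 CPM.

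ENSONIT00000000590.1 was also higher in every cleaner species than in every non-cleaner species. Its mean was 1504 ± 308 CPM (SD, n = 9) in Halichoeres, 1190.1 ± 338 CPM (SD, n = 10) in Hemigymnus and 1600.2 ± 383 CPM (SD, n = 10) in Thalassoma. In Coris it was 169.7 ± 141 CPM (SD, n = 9) and in Labrichthys 262 ± 149.6 CPM (SD, n = 8). Its log2 fold change was 2.799 (SE 0.18, edgeR adjusted p = 2.68e-19), and all 29 cleaner fish were above all 17 non-cleaner fish, with a lowest cleaner value of 558 CPM and a highest non-cleaner value of 492 CPM. The former was 2 counts in the library labelled Hemigymnus melapterus 4 and the latter 4 counts in the shallow library labelled Coris batuensis 10. The TMM factors of these libraries were 0.695 and 0.931, and a lower factor raises the CPM. The order of these 2 values, and with it the full separation, therefore depends on the scaling. The next lowest cleaner value was 977 CPM, and the highest value in Labrichthys was 465 CPM. Neither transcript differed past the threshold between any 2 species of the same status (edgeR adjusted p from 0.0755 to 0.912 over the 4 pairs and both transcripts). The files do not pair these identifiers with gene names, so what the transcripts encode is not stated here.

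The 2 transcripts with the largest falls in cleaners among those past the threshold were chosen after their values were seen. ENSONIT00000000964.1 had 318 counts in the 8 Labrichthys libraries and 16 counts in the other 38 libraries. Its mean was 1922 ± 380.3 CPM (SD, n = 8) in Labrichthys, 18.1 ± 27.3 CPM (SD, n = 9) in the other non-cleaner, Coris, and 34.1 ± 40.7 CPM (SD, n = 10) in Thalassoma, the highest of the cleaners. The fitted status log2 fold change of -3.18 (SE 0.66, edgeR adjusted p = 9.35e-05), which was not past the threshold with the species as a random block (limma-voom), rested on Labrichthys, since Coris did not differ past the threshold from any cleaner species (edgeR adjusted p from 0.455 to 0.780), and because some species had 3 counts or fewer the fitted size depends on the model. ENSONIT00000011303.1 averaged 3995 ± 1051 CPM (SD, n = 9) in Coris, 593 ± 131 CPM (SD, n = 8) in Labrichthys, 552 ± 262 CPM (SD, n = 10) in Thalassoma, 92.0 ± 105 CPM (SD, n = 9) in Halichoeres and 82.1 ± 71.2 CPM (SD, n = 10) in Hemigymnus. Its status log2 fold change was -3.15 (SE 0.20, edgeR adjusted p = 6.74e-19), and without Coris it was -1.78. The log2 fold change against Labrichthys was -2.60 in Halichoeres, -2.69 in Hemigymnus and -0.09 in Thalassoma (edgeR adjusted p = 1.46e-07, 1.62e-07 and 0.811).

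**Figure D2:**
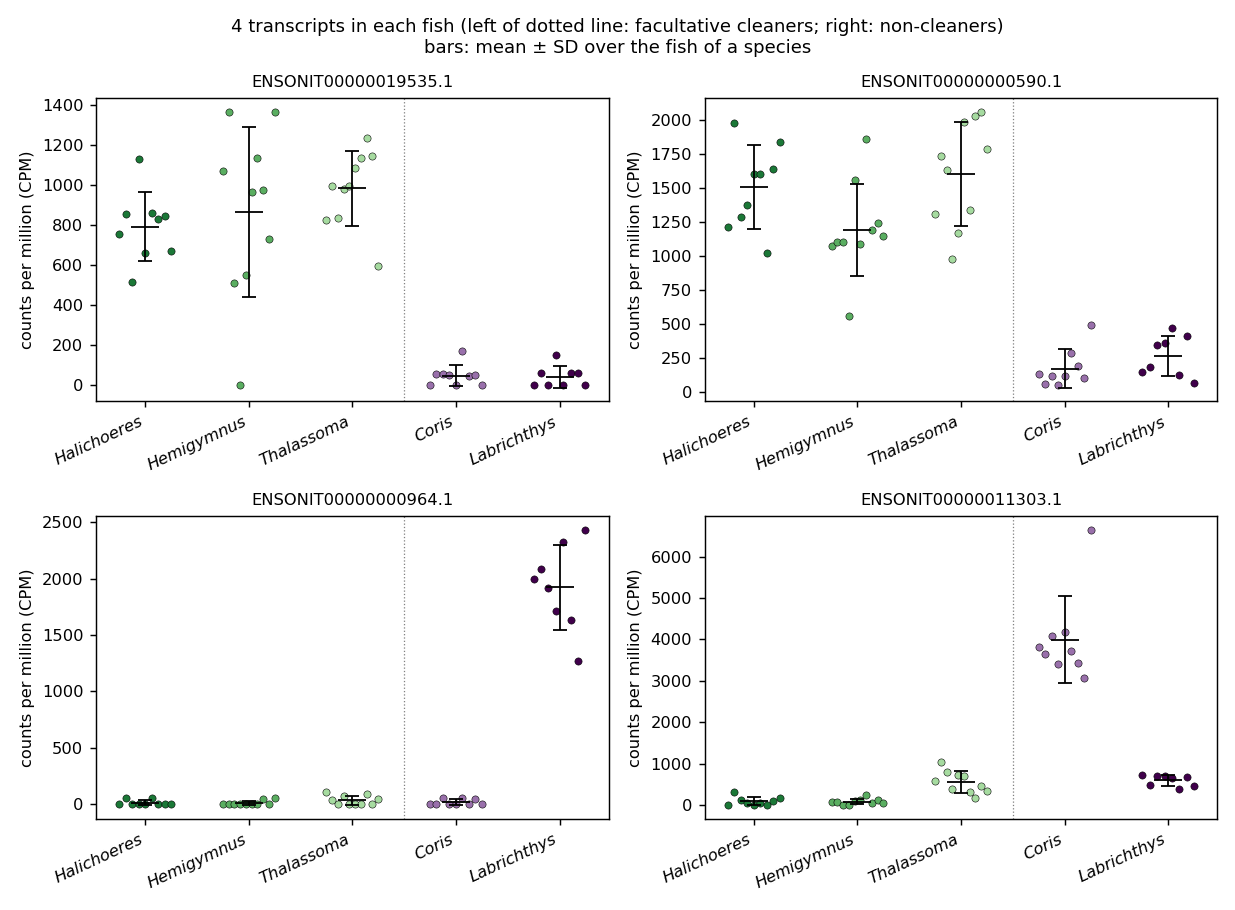
CPM (vertical axes) of the 4 named transcripts in each of the 46 fish, by species (horizontal axes), with mean ± SD of each species and a dotted line between the 3 cleaner and the 2 non-cleaner species. The upper 2 transcripts are higher in all 3 cleaner species, with means of 790 to 982 CPM and of 1190 to 1600 CPM, the lower left one stands out in Labrichthys (1922 CPM) and the lower right one in Coris (3995 CPM).

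Over all 720 transcripts, 272 differed between the mean of the cleaner species and the mean of the non-cleaner species at an adjusted p below 0.05 (edgeR quasi-likelihood test over fish). Of these, 126 were higher and 146 lower in cleaners, and 55 and 39 had an absolute log2 fold change of at least 1. Without the 3 libraries described above the counts were 125 and 166 of 701 tested, and 111 of the 126 and 144 of the 146 were called again in the same direction. With the species as a random block (limma-voom, with a consensus correlation of 0.391 within species over the 46 libraries), 5 transcripts were higher and 2 lower, of which 5 and 1 were among the 126 and 146. The random-block test applied 1 shared correlation to all transcripts and still counted fish, so it does not make the species the replicates of status.

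A stricter count asked for the same direction in all 6 comparisons of a cleaner species with a non-cleaner species. Both ENSONIT00000019535.1 and ENSONIT00000000590.1 met it, with smallest log2 fold changes over the 6 comparisons of 3.79 and 2.18. In all, 8 transcripts were higher in every cleaner species, with status log2 fold changes between 0.96 and 4.04, and 0 were lower in every cleaner species by edgeR. At an unadjusted p below 0.05 in all 6 comparisons 6 were lower, and DESeq2 called 2 lower. Without the 3 libraries described above 8 were higher, 7 of them among the first 8, and 3 were lower. In the Ldim_g counts 8 genes were higher and 13 lower of 753 tested.

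The same counts were made for all 10 ways of setting 2 of the 5 species against the other 3. The split by cleaning status gave 272 transcripts past the threshold, and the other splits gave 241 to 348. For transcripts that met all 6 comparisons, the split by status gave 8 and the other splits gave 4 to 25, the highest with Halichoeres and Thalassoma set apart. In the Ldim_g counts the split by status gave 379 and 21 genes, and the other splits gave 339 to 444 and 8 to 45. With the 3 libraries described above left out, the split by status gave 291 and 11 transcripts, and the other splits gave 293 to 360 and 9 to 32. The 32 came with Halichoeres and Coris set apart, and Halichoeres and Thalassoma then gave 28. Status accounted for 24.5% of the variance between the 5 species means, where the mean over the 10 splits is 25%, and species accounted for 50.7% of the variance between libraries.

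**Figure D3:**
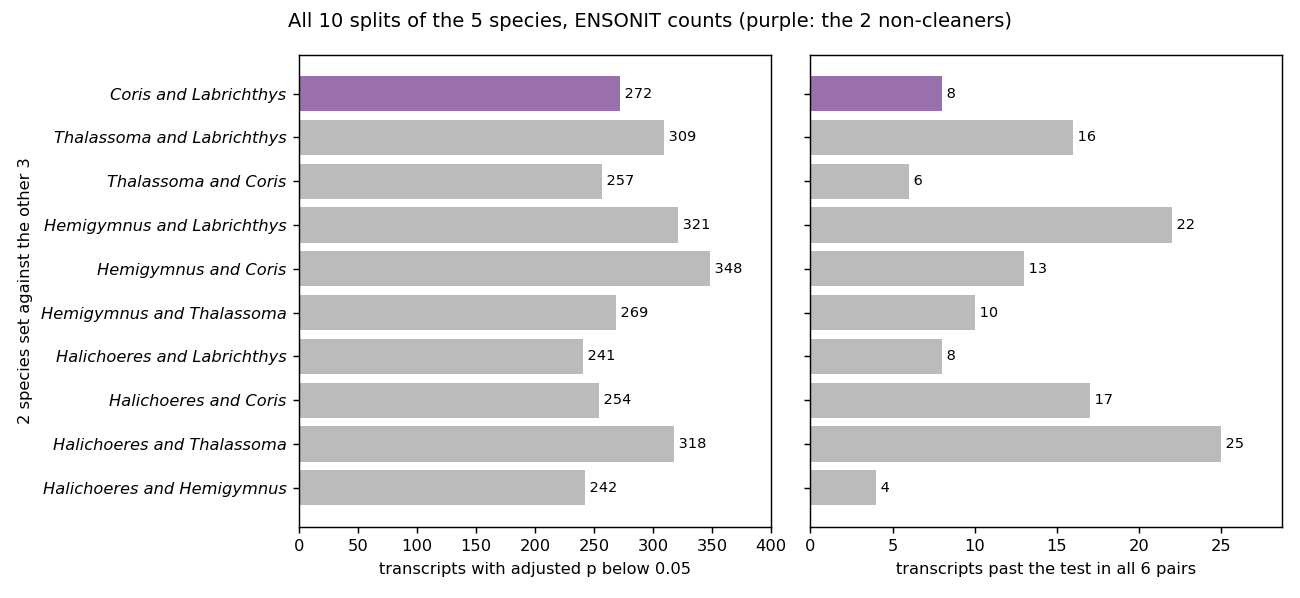
Number of transcripts past an adjusted p of 0.05 (left, horizontal axis) and number past it in all 6 species comparisons in 1 direction (right, horizontal axis) for each of the 10 splits of the 5 species, named by the 2 species set against the other 3 (vertical axis). The purple bars are the split by cleaning status, at 272 and 8 transcripts, and lie within the range of the other splits, 241 to 348 and 4 to 25.

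With 1 value per species, a limma test of 3 species against 2 called 2 of 720 transcripts, ENSONIT00000019535.1 and ENSONIT00000000590.1, both higher in all 3 cleaner species (limma adjusted p = 0.0244 for each). Their log2 differences between species means were 2.71 and 2.37 on the log2-CPM scale with a prior count of 2, which understates changes of low transcripts. At an unadjusted p below 0.05, which a share of about 0.05 would pass by chance, there were 41 of 720 transcripts. With a filter on a median of at least 1 CPM in each species, limma called 1 of 2962 transcripts. Without the 2 libraries nearest to another species ENSONIT00000019535.1 was no longer called (limma adjusted p = 0.0519), while without all 3 libraries both were (adjusted p = 0.0280). In the Ldim_g counts limma called 0 of 753 genes, with 32 at an unadjusted p below 0.05 and a lowest adjusted p of 0.404. The limma test took the species as independent of each other, without regard to their relatedness. It was run for the split by status only, so no other split of the species stands beside it.

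Species of the same status differed from each other in about as many transcripts as species of different status. The 4 pairs within a status had 225 to 331 transcripts past an edgeR adjusted p of 0.05, and the 6 pairs across status had 211 to 315. Hemigymnus and Thalassoma, both cleaners, differed in the most transcripts, 331, with a median absolute log2 fold change of 0.51. Halichoeres and Coris, a cleaner and a non-cleaner, differed in the fewest transcripts, 211, with a median of 0.41. By the median itself the highest pair was Hemigymnus and Labrichthys (0.52) and the lowest Halichoeres and Thalassoma (0.40). The 2 non-cleaners, Coris and Labrichthys, differed in 255. Halichoeres and Thalassoma, which include the 2 libraries nearest to another species, differed in 225, and in 311 without the 3 libraries described above. Without these libraries the pairs within a status had 292 to 349 transcripts and the pairs across status 253 to 360. The pair that differed most was then Thalassoma and Coris, a cleaner and a non-cleaner, with 360, and Hemigymnus and Thalassoma had 349. The Pearson correlation of species means across transcripts averaged 0.792 ± 0.041 (SD, 4 pairs) within a status and 0.790 ± 0.033 (SD, 6 pairs) across status. The exact permutation of the 5 species gave a two-sided p = 1, with a smallest possible p of 0.1. The averages without the 3 libraries were 0.765 ± 0.031 (SD, 4 pairs) within a status and 0.777 ± 0.040 (SD, 6 pairs) across status, exact permutation p = 0.5.

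**Figure D4:**
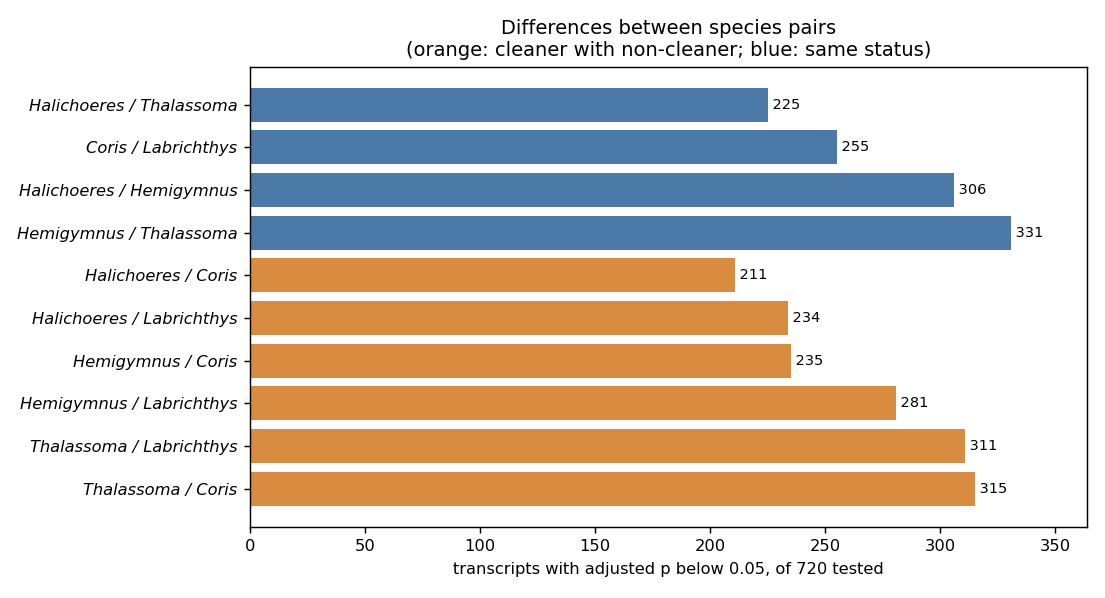
Number of the 720 tested transcripts with an edgeR adjusted p below 0.05 (horizontal axis) in each of the 10 pairs of species (vertical axis). Orange bars are pairs of a cleaner with a non-cleaner, from 211 to 315 transcripts, and blue bars are pairs of the same status, from 225 to 331, so that the ranges overlap.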

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

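The tests of the label exchange, of mixed libraries, of the splits of the species and of reads lost at one reference were chosen after the patterns were seen, and the tests on Hemigymnus melapterus 4 after that library's own values were seen but before those of the thinned libraries. Single libraries were picked out where the gap to the nearest library of their species exceeded Dixon's 95% critical value. This happened in 21 of 60 groups of library measures and in 4 of 20 groups of named transcripts, where chance gives about 1 in 20.

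The libraries labelled Thalassoma lunare 4 and Halichoeres melanurus 2 had the lowest correlations among the libraries of their labelled species, 0.742 and 0.714 in the ENSONIT counts and 0.776 and 0.756 in the Ldim_g counts. Mixtures near equal parts are argued against, on a scale where the mean of Halichoeres is at 0% and that of Thalassoma at 100%. Halichoeres melanurus 2 lay at 99.3% and Thalassoma lunare 4 at 7.70% in the ENSONIT counts (97.2% and 4.20% in the Ldim_g counts). A mixture near equal parts would put both between 20% and 80%. In the ENSONIT counts the other libraries lay at -2.32% to 13.2% for Halichoeres and at 93.7% to 101% for Thalassoma. The positions rest on the counts that picked these libraries, and a small admixture is not excluded. Of 90 trial exchanges of 1 label between the 2 species, that of these 2 libraries gave the most transcripts between the species, 292. As labelled there were 225, and the highest other exchange gave 251. These calls rest on the counts that picked the libraries. An exchange of the 2 labels stays open as a candidate explanation. The share of unaligned reads, a measure not used to pick these libraries, does not settle it. This share, 62.1% in Halichoeres melanurus 2, lay within the 58.2% to 62.5% of the other libraries labelled Thalassoma and above the 57.5% to 60.3% of the other libraries labelled Halichoeres, while the 60.7% of Thalassoma lunare 4 lay above that range too and within that of its own label, where an exchange would put it in the lower range. The total of reads in the second set, also not used to pick them, went with the labels. Thalassoma lunare 4 had 1050567 reads, above the 357646 to 916956 of the other libraries labelled Halichoeres. Halichoeres melanurus 2 had 718472, below the 759231 to 1072478 of the other libraries labelled Thalassoma. Totals varied widely within a species, so they do not settle the question either. No biological explanation was tested.

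The library labelled Hemigymnus melapterus 4 had 1676 detected transcripts and 1607 detected genes, gave 21.7% and 16.5% of its counts to its 10 highest features, and correlated with its species at 0.544 and 0.725 in the ENSONIT and Ldim_g counts. Of its reads 18.0% fell in genes, where the other Hemigymnus libraries had 4.58% to 5.95%, and 58.5% of its aligned reads lay outside genes, where the others had 82.3% to 85.2%. Lower depth alone is argued against: the other 9 libraries thinned to 6936 counts detected 2610 to 2990 transcripts and had correlations, recomputed with the thinned totals, of 0.854 to 0.886, where this library had 0.525. With its 10 highest features left out of the correlation it was 0.495, below the 0.832 to 0.867 of the thinned libraries treated alike, so the low correlation did not rest on those values. Library totals still included these features, so whether they took counts from the other transcripts was not tested. Damage to the RNA or a failed library step was not tested, and no biological explanation was tested.

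ENSONIT00000019535.1 and ENSONIT00000000590.1 were several-fold higher in each cleaner than in each non-cleaner species, and a loss of reads of both non-cleaner species at one reference stays open as an explanation beside an untested difference in abundance tied to status. Among Ldim_g genes higher in all 6 comparisons, the largest of the smallest log2 folds was 1.38, below the 2.18 and 3.79 of these transcripts. The 2 sets share no identifiers, so whether the same genes were measured is unknown, and the 2 explanations cannot be told apart with these counts.

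Other single values stood apart. Coris batuensis 10 had the lowest ENSONIT count of its species (14800), few detected transcripts (4732) and genes (2910), the lowest total of reads (287241) and the lowest correlations with its species (0.869 and 0.911). Halichoeres melanurus 5 detected 5412 transcripts and had 357646 reads in all, both the lowest of its species. Thalassoma lunare 8 had the lowest unaligned share of its species, 58.2%. ENSONIT00000019535.1 reached 172 CPM in Coris batuensis 6 and 152 CPM in Labrichthys unilineatus 5, which are 3 counts at most. ENSONIT00000011303.1 reached 242 CPM in Hemigymnus melapterus 7 and 6645 CPM in Coris batuensis 10. Reads outside the counts compared here formed a large part of the second set: 36.6% of all reads were listed as aligned outside any gene, against 4.81% in genes.

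Regrouping the fish gave no result as large as the real one. With species labels shuffled over the 46 fish, 1 of 100 groupings, the real one, gave as many transcripts past the status contrast (272, highest other 37) and as many in all 6 comparisons (8, highest other 0). For each of the 10 species pairs, again 1 of 100 groupings of the pair's fish, the real one, gave as many transcripts. The real and highest other counts were 306 and 126 for Halichoeres with Hemigymnus, 225 and 47 for Halichoeres with Thalassoma, 211 and 52 for Halichoeres with Coris, and 234 and 150 for Halichoeres with Labrichthys. They were 331 and 196 for Hemigymnus with Thalassoma, 235 and 101 for Hemigymnus with Coris, and 281 and 211 for Hemigymnus with Labrichthys. They were 315 and 133 for Thalassoma with Coris, 311 and 30 for Thalassoma with Labrichthys, and 255 and 93 for Coris with Labrichthys. As 44 of 46 libraries already lay nearest to their own labelled species, this outcome was close to fixed in advance. It concerns differences between species and adds no support for status, since status varies only between species.

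Over the species themselves, 5 of the 10 splits gave at least as many transcripts past the threshold as the split by status (272, highest other 348) and 8 of the 10 gave at least as many in all 6 comparisons (8, highest other 25). The 10 splits are too few for a share below 0.1. Without the 3 libraries that stood apart, the split by status gave the fewest transcripts past the threshold, 291, and the other splits gave 293 to 360. In the Ldim_g counts without these libraries the split by status gave 420 genes, and the other splits gave 396 to 488.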

How the results depend on the processing

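Settings that left libraries out singly or together, and the species-level test on the Ldim_g counts, were chosen after seeing the data. Of the counts compared under other settings, 134 stayed within 1.5 times the main value or on the same side of the test, 83 moved further and 3 reversed; causes were not tested except where the setting itself removes or adds features, samples or depth. The log2 fold change of ENSONIT00000019535.1 ranged from 3.97 to 4.21 and that of ENSONIT00000000590.1 from 2.42 to 3.22 over 17 settings each, past the threshold in all of them. These settings were tests over fish. The species-level test without the 2 libraries nearest to another species lost ENSONIT00000019535.1 (limma adjusted p = 0.0519) and kept ENSONIT00000000590.1 (limma adjusted p = 0.0475). ENSONIT00000011303.1 ranged from -4.49 to -1.78 over 18 settings, past the threshold in all. ENSONIT00000000964.1 ranged from -6.29 to -2.94 over 15 settings and lost its call with the species as a random block (-3.002). Under thinning only ENSONIT00000011303.1 of the 4 had enough counts to be tested. The number of assigned counts limits the test to 720 of the 25328 transcripts with a count.

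With DESeq2 size factors or upper-quartile scaling no count moved by over 1.5 times. The DESeq2 Wald test called 2 transcripts lower in all 6 comparisons (main 0). In the Ldim_g counts 200 genes were higher by status and 13 lower in all 6 comparisons, Halichoeres with Labrichthys gave 386 and Coris with Labrichthys 383, and the species-level test gave 0 (32 at an unadjusted p below 0.05). The cleaner minus non-cleaner differences of library measures reversed there, none past its test: -485 counts (main 271), -8.11 features detected (main 56.5) and 0.309 percentage points in the 10 highest features (main -0.294).

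Without a filter 25328 transcripts were tested: 376 were higher and 627 lower by status, 4 and 3 in all 6 comparisons. The pairs of Halichoeres gave 1269 with Hemigymnus, 759 with Thalassoma, 953 with Coris and 1266 with Labrichthys; Hemigymnus gave 1867 with Thalassoma, 1337 with Coris and 1496 with Labrichthys; Thalassoma gave 1424 with Coris and 1421 with Labrichthys, and Coris with Labrichthys 1319. With a median of at least 1 CPM in each species 2962 were tested: 206 higher, 282 lower, 6 lower in all 6 comparisons and 1 at the species level. There Halichoeres gave 397 with Coris and 470 with Labrichthys, Hemigymnus 591 with Thalassoma, 449 with Coris and 517 with Labrichthys, Thalassoma 576 with Coris and 560 with Labrichthys, and Coris with Labrichthys 514.

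A minimum absolute log2 fold change of 1 left 55 higher and 39 lower, and 4 higher in all 6 comparisons. Halichoeres then gave 170 with Hemigymnus, 132 with Thalassoma and 121 with Coris, Hemigymnus 196 with Thalassoma, 143 with Coris and 171 with Labrichthys, Thalassoma 174 with Coris and 169 with Labrichthys, and Coris with Labrichthys 167. Thinned to 6936 counts, with 160 tested, 25 were higher, 28 lower and 1 higher in all 6 comparisons. Halichoeres then gave 47 with Hemigymnus, 27 with Thalassoma, 23 with Coris and 37 with Labrichthys, Hemigymnus 69 with Thalassoma, 50 with Coris and 47 with Labrichthys, Thalassoma 46 with Coris and 45 with Labrichthys, and Coris with Labrichthys 38.

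Leaving out a species lowers the number of comparisons a transcript must pass. Higher and lower in all remaining comparisons were 15 and 12 without Halichoeres, 25 and 28 without Hemigymnus, 33 and 46 without Coris, and 23 and 29 without Labrichthys; without Thalassoma 4 were lower. With the species as a random block (limma-voom) 5 were higher and 2 lower by status.

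No pairing of the fish by the sample numbers shared by the species was seen: deviations from species means correlated at -0.017 on average over 84 pairs of libraries with the same number, 5 of them over 0.1, and 3 of 46 libraries matched their own number best. With so few assigned counts these deviations hold much counting error, so a batch shared by number is not excluded. With the number as a replicate block 119 were higher and 140 lower by status, 7 higher and 1 lower in all 6 comparisons, and no other count moved by over 1.5 times.

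Without the 2 libraries nearest to another species 1 transcript was lower in all 6 comparisons and 1 was called at the species level. Without these and Hemigymnus melapterus 4, 3 were lower in all 6. In the Ldim_g counts without the 3 libraries 208 were higher by status, 14 lower in all 6 comparisons and 0 called at the species level (27 at an unadjusted p below 0.05). Halichoeres then gave 410 with Thalassoma, 365 with Coris and 443 with Labrichthys, Hemigymnus 413 with Coris and 440 with Labrichthys, Thalassoma 473 with Coris and 472 with Labrichthys, and Coris with Labrichthys 441. Leaving out only Hemigymnus melapterus 4 moved no count by over 1.5 times. Leaving out only Coris batuensis 10, run for the status contrast and the transcripts in all 6 comparisons, moved neither by over 1.5 times. The settings planned for gene lists were not run, since no list could be matched to identifiers. ENSONIT00000000964.1 had no value with the median filter or without Labrichthys, where it was not tested.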

Other observations

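The counts and shares without the 3 libraries that stood apart were chosen after seeing the data. Each species had transcripts that set it apart from the 4 others, past an edgeR adjusted p of 0.05 in all 4 pairs and in 1 direction. Labrichthys had 40 such transcripts that were higher and 25 that were lower, Hemigymnus 38 and 35, Thalassoma 34 and 26, Coris 28 and 14, and Halichoeres 15 and 8. A transcript could pass the filter through 1 species alone, as ENSONIT00000000964.1 did through Labrichthys. The numbers of higher and lower transcripts are therefore not on equal terms. Without the 3 libraries that stood apart the counts were 47 and 28 in Labrichthys, 39 and 39 in Hemigymnus, 53 and 43 in Thalassoma, 34 and 19 in Coris, and 23 and 19 in Halichoeres. Among Ldim_g genes the higher and lower ones were 76 and 46 in Labrichthys, 59 and 57 in Hemigymnus, 42 and 41 in Thalassoma, 30 and 38 in Coris, and 27 and 14 in Halichoeres. Without the 3 libraries these genes were 85 and 52 in Labrichthys, 67 and 57 in Hemigymnus, and 67 and 64 in Thalassoma. They were then 41 and 43 in Coris and 40 and 31 in Halichoeres.

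Without the 3 libraries the biological coefficient of variation of the ENSONIT counts was 0.154 in Thalassoma (n = 9), 0.185 in Halichoeres (n = 8), 0.185 in Coris (n = 9), 0.216 in Hemigymnus (n = 9) and 0.221 in Labrichthys (n = 8). Leaving out the 3 libraries raised the share of variance between libraries that species account for from 50.7% to 65.4%, and the share of the variance between species means that status accounts for went from 24.5% to 22.6%. Of the 10 splits of the species, that by status included, 6 gave a share at least as large as status with all libraries (others 19.4% to 29.4%) and 9 without the 3 libraries (others 20.7% to 31.0%). Differences in the coefficients of variation were not tested.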
